A study of Mus musculus with 4 samples.

How the data were processed

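Small intestinal epithelium was taken from 3 wild-type mice and 3 mice lacking Ifnlr1 in the intestinal epithelium after 11 Gy of gamma irradiation with head, thorax and upper limbs shielded. The time of collection is given as 96 h after irradiation in the series design and as 3 days in the extraction protocol, and the 2 were not reconciled. Per the labels, live cells positive for EPCAM and negative for CD45 were sorted, each mouse was marked with its own streptavidin-PE hashtag, and the cells of a genotype were pooled into 1 sample for 10x Genomics 3′ libraries of mRNA and hashtags. The labels name 2 independent experiments, of which the first is reported and the second was not analysed here. The authors ran Cell Ranger 7.0.1 against mm10, and Seurat 4.1.0 is named without its role. The deposited matrices hold raw UMI counts, whole numbers without normalization, for 32285 genes and 3 hashtags per library, in barcodes that Cell Ranger called as cells. Whether intronic reads were counted is not stated. The hashtag UMIs summed to 19572643 in the WT and 21267373 in the KO library, and the median gene UMIs per barcode were 6769 and 8232.5.

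Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 25% mitochondrial UMIs. This kept 5563 of 10453 WT barcodes (53.2%) and 4028 of 7370 KO barcodes (54.7%), and most of the loss was at the mitochondrial limit, since 9826 and 6670 passed the UMI and gene minimums. The median mitochondrial share before filtering was 22.5% and 22.0%. Hashtags were assigned with HTODemux (Seurat 5.3.0, quantile 0.99). Of the barcodes past the filters, 549 (9.87%) in WT and 305 (7.57%) in KO were hashtag doublets and were left out, and 2241 (40.3%) and 855 (21.2%) carried no hashtag and were used in clustering but in no comparison between mice. A rule asking for a ratio of at least 3 between the highest and the next hashtag gave the same mouse for 2595 of 2773 assigned WT cells and 2850 of 2868 KO cells and another mouse for 0. Scrublet called 0 doublets in either library, fewer than the hashtags found, so it did not work on these cells and doublets of 1 mouse stay in. As an alternative, the highest 5% of its scores were left out.

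The 8737 cells were clustered with scanpy 1.11.5 (log-normalization, 2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2 at resolution 1), both libraries together without batch correction. The interferon-stimulated and antigen presentation lists and mitochondrial, ribosomal protein, haemoglobin and sex-linked marker genes were left out of the clustering. The 21 clusters were named from marker lists when the best class led the next by at least 0.15 in score (mean of each marker's CPM over its highest CPM in any cluster), at least 3 of its markers reached 20 CPM, and the 10 leading genes (seen in at least 25% of cells) held no more markers of another class than of its own. That lead was set after the clusters had been seen. Clusters that missed any of these 3 rules stayed unnamed. Names end in "-like" because they rest on transcripts alone.

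The mouse was the replicate. UMI counts were summed per mouse over all cells, and over each class with at least 20 cells in every mouse, which left enterocyte-like and goblet-like cells. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested with camera (limma 3.58.1, on voom values, with a preset correlation of 0.01 and again with an estimated one) and with fry, and adjusted over the lists tested in the same cells. Shares and list sums were compared by 2-sided exact permutation tests of 3 against 3 mice. A quasi-binomial fit of the shares served as description. Single-mouse shares have exact Clopper-Pearson 95% intervals, and a count of 0 is given with the share that 3 counts would make. Since all mice of a genotype shared a pool, these p-values compare mice within 2 pools.

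The 2 pools carried hashtags of the same numbers, and mice of equal number were treated as a block in an alternative fit. It is given beside the results because log CPM of the paired mice, with each genotype's mean taken out, correlated above 0.1 across genes for all 3 pairs (0.416, 0.854 and 0.638 in all cells, 0.665, 0.881 and 0.674 in enterocyte-like cells, 0.311, 0.734 and 0.430 in goblet-like cells). Other pairs correlated as well: WT1 with KO3 at 0.461 and WT3 with KO1 at 0.638 in all cells, so the block mostly takes out the distance of the mice with hashtag 2 from the rest. The labels state no pairing. Blocked and unblocked counts were computed in the same step.

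The 27 gene lists and the rule for naming genes were fixed before the data were examined. The lists are interferon-stimulated, antigen presentation, interferon receptor, pyroptosis, p53 targets, proliferation, villus bottom, mid villus, villus top, antimicrobial, lipid absorption, nutrient transport, Wnt targets, unfolded protein response, dissociation and oxidative phosphorylation, and markers of stem, regenerative, transit-amplifying, enterocyte, goblet, Paneth, enteroendocrine, tuft, immune, stromal and erythroid cells. Some genes stand in more than 1 list. By the naming rule, genes past the threshold with at least 50 CPM in 1 library were ranked by log2 fold change and the 10 highest and 10 lowest named for all cells, and the 5 highest and 5 lowest with at least 100 CPM for each class of at least 100 cells per library, without mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed genes. The rule also takes the 4 most abundant members of each list and 24 genes of interferon response, pyroptosis, stem cells and repair. Without a block it names none by rank, so ranked names come from the blocked fit, where 64, 584 and 5 genes met it in all, enterocyte-like and goblet-like cells. List members past the threshold, Gip, Rtp4, Sis, Ghrl, Nlrp9b and Jak2 where they fall outside the rule, were chosen after their values were seen. Named genes were matched to GENCODE vM21 (GRCm38) by gene identifier.

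Alternatives were DESeq2 1.42.0, limma-trend on mean per-cell CPM, RLE or no scaling between libraries, no filter or at least 50 CPM on genes, leaving out the 20 most abundant genes, each mouse in turn, a UMI minimum of 500 or 2000, a mitochondrial limit of 10% or none, hashtag doublets kept, the hashtag ratio rule, equal class shares, resolutions 0.5 and 2, clustering of each library alone or with all variable genes, and cells thinned to 2000 UMIs (which drops 488 WT and 58 KO cells with fewer). The Scrublet scores, the enterocyte-like class with the unnamed cluster that scored nearest to it, the leaving out of both mice with hashtag 2 and combinations with the block were added after the data had been seen. The tests were tried on simulated data: 200 genes were given a true change in counts with the estimated dispersions. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.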

Results

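Single-cell RNA sequencing was used on small intestinal epithelial cells of irradiated mice, which were either wild type (WT) or lacked the interferon-λ receptor gene Ifnlr1 in the intestinal epithelium (Villin-Cre with floxed Ifnlr1, written KO here). There were 3 mice of each genotype, and each mouse carried its own hashtag, an antibody-borne DNA barcode read in every cell. The cells of the 3 mice of a genotype were pooled in 1 library, so genotype and pool cannot be told apart in any comparison given here. The WT library held 10453 barcodes with 102915321 gene UMIs (unique molecular identifiers, 1 per captured transcript), and the KO library held 7370 barcodes with 110960113. After filtering and assignment by hashtag, 845, 866 and 1062 cells remained from WT mice 1 to 3, and 1030, 995 and 843 from KO mice 1 to 3. Their summed UMIs were 11142876, 21067444 and 13936000 in WT mice and 14731105, 35999518 and 15440446 in KO mice. The 2 mice with hashtag number 2 (WT2 and KO2) stood apart from the others in depth, with a median of 12657 and 20575 UMIs per cell against 8527 to 11623 in the other 4. Values are means ± SD over 3 mice per genotype in CPM. For list sums, CPM are UMI counts scaled by the total of each mouse. For single genes, that total was adjusted by the TMM scaling used in the tests. Gene values and list sums are therefore not on the same scale. Log2 fold changes are KO over WT with their standard error (SE).

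All cells of a mouse were first summed, to ask how loss of the receptor altered the irradiated epithelium as a whole. The targeted gene itself, Ifnlr1 (ENSMUSG00000062157, mm10 chromosome 4, 135686287 to 135708181), stood at 23.7 ± 9.0 CPM in WT and 20.8 ± 6.12 CPM in KO mice, a log2 fold change of −0.19 (SE 0.38). The labels do not name the deleted part of the gene, and counts from the 3′ end of a transcript need not cover it, so this value does not check the deletion. Interferon-stimulated genes, the antiviral program that interferons switch on, were lower in KO mice. The summed list stood at 3647.5 ± 839 CPM in WT and 1954 ± 549.9 CPM in KO, a ratio of 0.536, with every KO mouse under every WT mouse (exact permutation p = 0.1, the smallest that 3 against 3 mice allow). Ifit1, an inhibitor of viral translation, stood at 83.4 ± 27.1 against 9.35 ± 5.15 CPM, and Isg15, a ubiquitin-like modifier, at 322 ± 162 against 55.4 ± 29.2 CPM. Mt1, a metal-binding stress protein, was higher at 312 ± 229 against 1087 ± 441 CPM.

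As a set, the 48 measured interferon-stimulated genes fell, with a median log2 fold change of −1.13 (camera, adjusted p = 1.78e-56), and the call was lost when the correlation between genes was estimated (adjusted p = 0.220 with an estimated correlation). None of the 48 passed over all genes and 24 were lower when adjusted over the list alone. With the hashtag number as a block, 28 passed over all genes, all lower, and 46 were lower and 2 higher when adjusted over the list alone. The antigen presentation list, made of MHC molecules, their loading machinery and interferon-γ-type GTPases, fell with a median of −0.83 over 29 genes (adjusted p = 6.24e-25, and adjusted p = 0.220 with an estimated correlation), with 8 lower when adjusted over the list alone. Its sums overlapped between genotypes, at 4715 ± 859 CPM in WT and 3664 ± 1039 CPM in KO (exact permutation p = 0.5). Its members past the threshold with the block were H2-Aa (−3.93), Irgm2 (−3.02), Igtp (−2.51), H2-Ab1 (−2.30), Gbp7 (−2.13), Cxcl10 (−1.77) and Tap1 (−1.14). Genes of the enterocyte villus top, where mature absorptive cells shed, fell with a median of −0.71 over 14 genes (adjusted p = 3.20e-04, and adjusted p = 0.927 with an estimated correlation). The other 23 lists tested in all cells did not pass without the block. There median and test differed in sign for regenerative (median −0.24), nutrient transport (−0.13), immune (−0.01) and stromal (−0.17), all directed up, and for villus bottom (0.11), directed down. With the block, camera at the preset correlation passed proliferation (adjusted p = 7.33e-07), transit-amplifying (1.16e-04), enterocyte (6.08e-04) and lipid absorption (0.00372). It also passed goblet (0.00610), interferon receptor (0.00712), oxidative phosphorylation (0.0114) and antimicrobial (0.0187) lists. With an estimated correlation these gave 0.525 to 0.885.

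The edgeR quasi-likelihood test called 0 of 12944 genes, with 232 at an unadjusted p under 0.05, and DESeq2 called 36 (5 higher and 31 lower in KO). If no gene differed, a share of about 0.05 of the genes would be expected under that p, and 232 is fewer. Each such unadjusted count given below was also under that share. The block for hashtag number, which takes out the distance between the mice with hashtag 2 and the others, gave 152 genes, 26 higher and 126 lower. Of the genes named by rule from that fit, the lowest were Ifit1 (−3.28), Isg15 (−2.56), H2-Ab1 (−2.30), the nitric oxide synthase Nos2 (−2.24), Oasl2 (−2.22), Ddx60 (−2.19), Rnf213 (−2.02), Slfn4 (−1.77), Ifit1bl1 (−1.70) and the fucosyltransferase Fut2 (−1.69). The highest were Mt1 (1.97), the ileal bile acid carrier Fabp6 (1.87), the histone gene Hist1h2ap (1.70), the arginase Arg2 (1.16) and Cox7a1 (0.81). Hist1h2ap stood at 47.8 CPM in WT2 and 175 CPM in KO2 and at 4.9 CPM or less in each other mouse. Arg2 was a leading gene of cluster 9, which held 78 cells of WT2, 131 of KO2 and 1 to 4 of each other mouse. Both counts depended on which mice were included: without WT2 and KO2, edgeR called 9 genes, 1 higher and 8 lower, and with the block and without the pair of hashtag 1, 2 or 3 it called 1212, 55 or 36.

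Enterocyte-like cells, the absorptive cells of the villus and the largest class, numbered 603, 529 and 862 in the WT mice and 749, 476 and 557 in the KO mice (5842327 to 12905446 UMIs per mouse). Within this class the interferon-stimulated list stood at 4630.4 ± 664 CPM in WT and 2382.5 ± 688 CPM in KO, a ratio of 0.515. The values were 4405, 4109 and 5378 CPM in the WT mice and 2873, 1597 and 2678 CPM in the KO mice (exact permutation p = 0.1). Isg15 was 434 ± 175 against 78.6 ± 33.0 CPM, Ifit1 115 ± 26.2 against 14.2 ± 7.36 CPM, and Oas1a, which makes the 2′-5′ oligoadenylates that switch on RNA decay, 36.2 ± 8.36 against 4.05 ± 1.71 CPM. For these 3 genes each KO mouse lay under each WT mouse. Ifnlr1 stood at 34.8 ± 10.1 against 30.3 ± 8.12 CPM (log2 fold change −0.20, SE 0.32) and its partner chain Il10rb at 59.8 ± 3.35 against 54.1 ± 3.23 CPM. The summed Paneth cell list, mostly defensins, was higher in each KO mouse than in each WT mouse, the summed villus top list overlapped between genotypes, and the pyroptosis list did not pass its test.

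**Figure D1:**
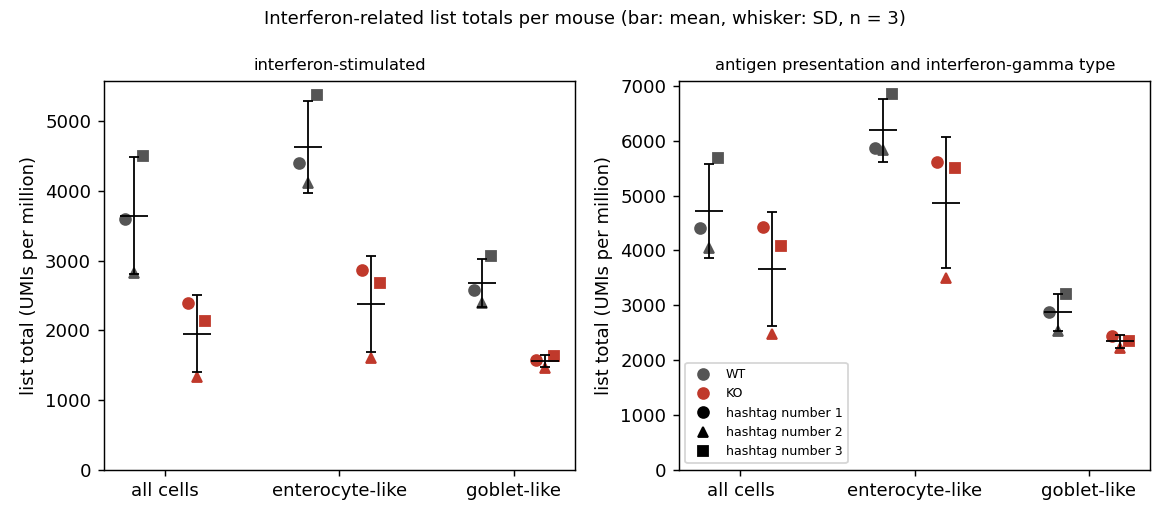
Summed CPM of the interferon-stimulated list (left) and the antigen presentation list (right) in all cells, enterocyte-like and goblet-like cells, with a point per WT (grey) or KO (red) mouse, shaped by hashtag number, and bars and whiskers for mean ± SD over 3 mice. In enterocyte-like cells the interferon-stimulated list lies between 4109 and 5378 CPM in WT mice and between 1597 and 2873 CPM in KO mice.

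The 48 measured interferon-stimulated genes fell as a set in enterocyte-like cells, with a median log2 fold change of −1.26 (camera, adjusted p = 3.11e-49, and adjusted p = 0.196 with an estimated correlation). None passed over all genes without the block, and 29 were lower when adjusted over the list alone. With the block 43 passed, all lower, from −5.32 in Ifi44 to −0.53 in Parp9, and 46 were lower when adjusted over the list alone. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818) had a log2 fold change of −2.46 (SE 0.47, adjusted p = 0.416) and with the block −2.49 (SE 0.20, adjusted p = 1.65e-04), with adjusted p from 4.96e-29 to 1 over the alternatives. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) had −3.02 (SE 0.46, adjusted p = 0.260) and with the block −3.12 (SE 0.30, adjusted p = 4.40e-04), with adjusted p from 3.51e-25 to 1. Oas1a (ENSMUSG00000052776, chromosome 5, 120896256 to 120907521) had −3.17 (SE 0.41, adjusted p = 0.179) and with the block −3.23 (SE 0.22, adjusted p = 8.86e-05), with adjusted p from 1.28e-26 to 1. Past the threshold with the block as well were the transcription factor Irf7 (−1.26), the nucleic acid sensor Zbp1 (−1.19), Ifi27l2b (−0.85) and Oasl1 (−1.16). The CPM of Irf7 overlapped between genotypes, at 340 ± 150 against 144 ± 68.8.

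Antigen presentation genes fell with them, with a median of −0.65 over 26 measured genes (adjusted p = 1.97e-15, and adjusted p = 0.196 with an estimated correlation), 9 lower when adjusted over the list alone, and 16 lower over all genes with the block. The MHC class II invariant chain Cd74 went from 216 ± 101 to 9.74 ± 7.28 CPM, and with the block its log2 fold change was −4.57. The MHC class I genes H2-K1 (2136 ± 735 against 1519 ± 607 CPM), H2-D1 (1208 ± 387 against 817 ± 272 CPM) and B2m (1483 ± 153 against 1027.5 ± 290 CPM) passed with the block at −0.52, −0.57 and −0.57, and the proteasome activator Psme2 stood at −0.03. The list of interferon receptors and their kinases had a median of −0.20 over 9 genes (adjusted p = 0.0578), and 1 of them, Jak2, passed with the block at −0.73. With the block this list passed camera at the preset correlation (adjusted p = 0.0220) and not with an estimated one (adjusted p = 0.663).

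Pyroptosis, the lytic cell death run by gasdermin pores, is named in the title of the study. The 25 measured genes of that list had a median of −0.08 (adjusted p = 0.358), and their sum was 2705.5 ± 194 CPM in WT and 2968 ± 151 CPM in KO (exact permutation p = 0.3). The pore protein Gsdmd stood at 582 ± 203 against 480 ± 207 CPM (log2 fold change −0.28, SE 0.46) and the inflammasome sensor Nlrp9b at 285 ± 94.6 against 304 ± 155 CPM. Members went both ways with the block, where Zbp1 (−1.19), Casp4 (−1.08), Ripk1 (−0.63) and Casp8 (−0.45) were lower and Nlrp6 (1.24), Il18 (0.98), Nlrp1b (0.84), Pycard (0.79) and Casp1 (0.65) were higher. Pycard stood at 445 CPM in WT2 and 858 CPM in KO2 and at 11 to 29 CPM in the other 4 mice. Gsdmc2, Gsdmc3 and Gsdmc4 were under the count filter, with a UMI in at most 5 of 2467 KO and 2 of 2957 WT enterocyte-like cells thinned to 2000 UMIs, too few to compare. Without thinning, where depth differs between mice, Gsdmc4 was seen in 17 of 3250 WT and 46 of 2504 KO enterocyte-like cells, mostly from WT2 (2.84%) and KO2 (8.19%), with 0.332% at most in the other 4 mice (exact permutation p = 0.7). In crypt progenitor-like cells, which are deeper, it was seen in 23.7% of WT and 26.9% of KO cells and Gsdmc2 in 17 of 131 and 27 of 182.

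Along the villus axis, the villus top list fell with a median of −0.69 over 14 genes (adjusted p = 1.36e-04, and adjusted p = 0.775 with an estimated correlation), and 12 members were lower with the block. Its sums overlapped between genotypes, with 46290 CPM in WT2 and 75601 CPM in KO1 (exact permutation p = 0.3 over the 6 mice). The lower members included the lipoproteins Apoa1 (39255 ± 14995 against 24150 ± 10178 CPM, −0.72 with the block), Apoa4 (−0.61) and Apob (−0.77), the purine enzymes Ada (−0.81) and Nt5e (−0.77), the growth factor receptor Egfr (−1.55) and the transcription factor Klf4 (−0.76). The general enterocyte list had a median of −0.25 (adjusted p = 0.124) and lipid absorption one of −0.16 (adjusted p = 0.232). With the block both passed camera at the preset correlation (adjusted p = 0.00921 and 0.0364), and with an estimated one both gave 0.663. The mid villus list stood at 0.17 (adjusted p = 0.364), and its sugar-handling members Sis (1.07) and Slc2a2 (1.04) and the fatty acid carrier Fabp1 (0.66) were higher with the block while Slc5a1 (−0.54) was lower. The villus bottom list stood at 0.45 (adjusted p = 0.573). Nutrient transport had a median of −0.04 and a mean of 0.10 (adjusted p = 0.556). The enterocyte-like clusters differed with genotype, since WT cells lay mostly in clusters 2, 3, 6 and 14 and KO cells mostly in clusters 4 and 16. Cluster 9 was held mostly by WT2 (78 cells) and KO2 (131 cells), with 1 to 4 cells from each other mouse.

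Paneth cell transcripts rose as a set in enterocyte-like cells, with a median of 0.74 over 12 genes (adjusted p = 1.39e-05, and adjusted p = 0.775 with an estimated correlation) and 3 higher when adjusted over the list alone. The list summed to 312 ± 40.5 CPM in WT and 656 ± 145 CPM in KO, a ratio of 2.10 (exact permutation p = 0.1). The antimicrobial peptide gene Defa30 (ENSMUSG00000074444, chromosome 8, 21134642 to 21135598) went from 40.0 ± 5.58 to 131 ± 30.2 CPM, with a log2 fold change of 1.71 (SE 0.25, adjusted p = 0.212) and 1.70 with the block. Defa22 (2.43), Defa21 (2.14), Defa26 (1.70), Defa24 (0.89) and Lyz1 (0.58) also passed with the block. A Paneth-like cell held a median of 41234 defensin UMIs in WT and 42169 in KO, against 2 and 8 in an enterocyte-like cell. Of the antimicrobial and mucosal defence list (median −0.15, adjusted p = 0.148), 6 members were lower with the block, among them Nos2 (−2.52), the oxidase Duox2 (−1.19), Saa1 (−1.02) and the lectin Reg3g (−0.85), and 2 were higher. Reg3b, its relative, stood at 24268 ± 14257 against 18499 ± 8209 CPM. Duox2 and Saa1 were also leading genes of an unnamed cluster left out of this class, which held 68 WT and 301 KO cells. Cluster 6, led by Duoxa2, Saa1, Nos2 and Duox2, was kept and held 241 and 22. The lower Duox2 and Saa1 may therefore follow from which cluster was named. Nos2 was also among the lowest genes with the block in all cells, where no cluster was left out. For Nos2 this argues against the naming of clusters as the whole cause.

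The proliferation list rose as a set with a median of 0.77 over 19 genes (adjusted p = 0.00610, and adjusted p = 0.775 with an estimated correlation), from sums of 155, 330 and 164 CPM in the WT mice and 191, 611 and 191 CPM in the KO mice. Without KO2 the median was −0.07. The transit-amplifying list had the same median (adjusted p = 0.0501). The p53 target list had a median of 0.16 (adjusted p = 0.611), although the cell cycle inhibitor Cdkn1a (376 ± 108 against 219.9 ± 37.4 CPM, −0.74) and the death gene Pmaip1 (−1.26) were lower and Bax (0.68) was higher with the block. The stem cell list had a median of 0.04 and a mean of −0.21, with its test directed down (adjusted p = 0.315). The Wnt target list likewise had a median of 0.04 and a mean of −0.10, with its test directed down (adjusted p = 0.145), and Axin2, a feedback inhibitor of Wnt signalling in both lists, stood at 42.3 ± 9.95 against 14.9 ± 5.64 CPM (−1.55 with the block). The sums of both lists were lower in each KO mouse than in each WT mouse (exact permutation p = 0.1 each). They were 161 ± 14.4 against 118 ± 9.82 CPM for stem cell and 118 ± 4.71 against 89.8 ± 7.21 CPM for Wnt targets. The differences were −43.8 and −28.6 CPM, and the fall of Axin2 alone was nearly as large as the second. That comparison is approximate, since the CPM of Axin2 carry the TMM scaling and the sums do not. The 2 sums therefore share 1 gene that may make up much of their fall, and they do not show that either list fell as a whole. Lgr5 was under the count filter, Olfm4 stood at 3.38 against 4.57 CPM, and the regenerative list had a median of −0.04 (adjusted p = 0.573), with Clu at −0.57 and Areg at 0.00. Clu was also a leading gene of the unnamed, mostly KO cluster left out of this class. Oxidative phosphorylation stood at 0.43 (adjusted p = 0.0501), with sums of 4114, 13186 and 3806 CPM in the WT mice and 5452, 17849 and 7453 CPM in the KO mice. The unfolded protein response stood at 0.32 (adjusted p = 0.830) and dissociation genes, a sign of handling stress, at −0.30 (adjusted p = 0.148). With the block, camera at the preset correlation passed oxidative phosphorylation (adjusted p = 4.85e-05), transit-amplifying (0.00921) and dissociation genes (0.00921). With an estimated correlation each of these gave 0.663.

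Markers of other cell types in this class were goblet (median −0.07, adjusted p = 0.720), tuft (0.16, adjusted p = 0.464) and enteroendocrine, whose median of −0.20 and mean of 0.13 differed in sign (adjusted p = 0.704). The hormone genes Gip (3.16) and Ghrl (2.79) were higher with the block and Cck (−1.36) and Nts (−1.33) lower. Epcam, on which cells were sorted, stood at 3304 ± 731 against 3179 ± 838 CPM. In all cells, Ptprc, which encodes the CD45 sorted against, stood at 2.15 against 2.36 CPM. The immune list there had a median of −0.01 and a mean of −0.34 with its test directed up (adjusted p = 0.442), and the stromal list a median of −0.17 and a mean of 0.13 over 3 measured genes (adjusted p = 0.736). All 14 stromal genes summed to 5.74 ± 1.94 CPM in WT and 10.0 ± 1.87 CPM in KO, higher in each KO mouse than in each WT mouse (exact permutation p = 0.1). Erythroid genes were under the filter and summed to 0.0872 CPM in WT and 0.331 CPM in KO.

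For single genes in enterocyte-like cells, edgeR called 0 of 10571, with 454 at an unadjusted p under 0.05, limma-trend on mean per-cell CPM called 38, and DESeq2 called 70 (14 higher and 56 lower). With the block edgeR called 2205, 1209 higher and 996 lower. All 2205 had the same direction without it. That lends them no support, since each hashtag number holds 1 mouse of each genotype and the block hardly moves the fold changes. The genes named by rule from that fit were Cd74, Ifit1, Isg15, Ddx60 (146 ± 39.4 against 27.6 ± 12.2 CPM, −2.49 with the block) and Rnf213 (165 ± 38.9 against 29.0 ± 3.55 CPM, −2.48). On the other side they were Defa30, Mt1 (345 ± 346 against 1389 ± 903 CPM, 2.28), Fabp6 (26.7 ± 10.3 against 119 ± 58.7 CPM, 2.11), the glutathione transferase Gsta1 (227 ± 313 against 555 ± 731 CPM, 1.47) and the chaperonin Hspe1 (48.5 ± 65.8 against 153 ± 223 CPM, 1.44). For Gsta1 and Hspe1 the SD exceeded the mean in both genotypes. Gsta1 was also a leading gene of cluster 9, which was held mostly by WT2 and KO2. Fabp6 was a leading gene of cluster 10, which held 21 WT and 59 KO cells. Without WT2 and KO2 the unblocked test called 1231 genes (513 higher and 718 lower), and 1019 of them were among the 2205. On simulated data the unblocked test recovered 0% of genes with a true log2 change of 1 or of 2. The blocked test recovered 77% and 95%, with 12 false among 184 calls. Each was tried on counts drawn from its own fit, with common dispersions of 0.207 and 0.0199, and the counts for the block had hashtag effects built in. The values therefore do not compare the 2 tests on like data, nor show that the blocked calls are sound.

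**Figure D2:**
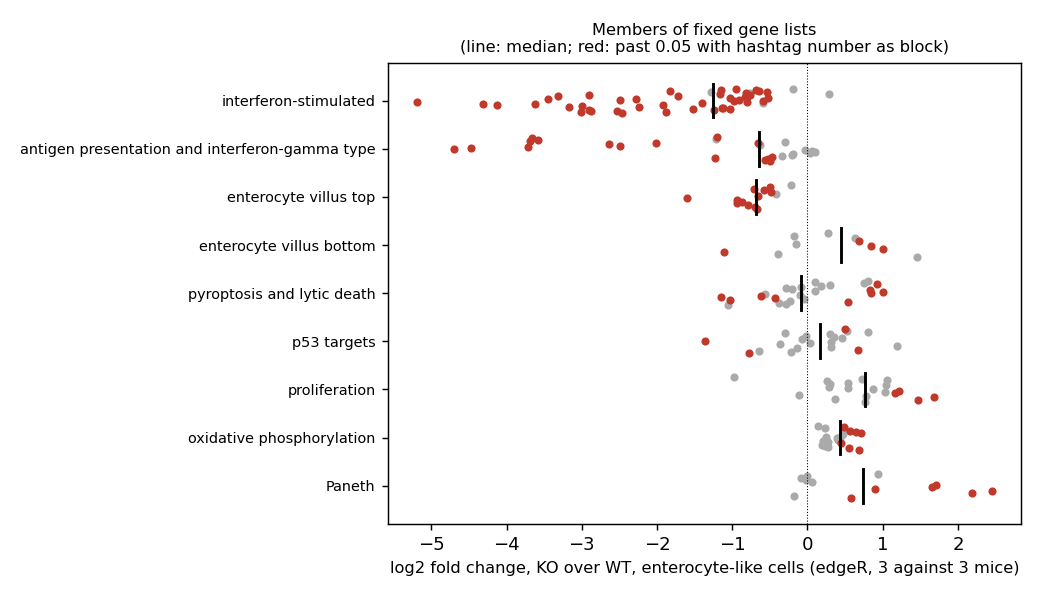
Log2 fold change (KO over WT) of the members of fixed gene lists in enterocyte-like cells, 1 point per gene, red where the gene passed with the hashtag number as block and grey where it did not, with the list's median as a line. The interferon-stimulated genes have a median of −1.26 and the Paneth genes one of 0.74.

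Goblet-like cells, which make mucus, numbered 135, 112 and 124 in the WT mice and 134, 162 and 145 in the KO mice (3147115 to 4921368 UMIs per mouse). Here 2 genes passed the edgeR test without a block, both named after their values were seen. Gip, an incretin hormone gene of enteroendocrine cells (ENSMUSG00000014351, chromosome 11, 96024545 to 96030831), rose from 0.562 ± 0.183 to 20.1 ± 6.89 CPM, with a log2 fold change of 5.07 (SE 0.45, adjusted p = 0.0316). Rtp4, an interferon-stimulated chaperone, fell from 21.2 ± 6.61 to 0.809 ± 0.219 CPM, with a log2 fold change of −4.65 (SE 0.38, adjusted p = 0.0316). In both genes all 3 KO mice lay outside the WT range. In all cells Gip stood at 77.4 ± 107 against 450.2 ± 236 CPM and did not pass (adjusted p = 0.989), and a second hormone gene, Ghrl, stood at 0.188 ± 0.185 against 8.03 ± 0.180 CPM in goblet-like cells and did not pass either (adjusted p = 0.0657). Both hormone genes were also higher with the block in enterocyte-like cells. Free RNA from enteroendocrine cells was not tested for them, so a change within goblet-like cells is not shown.

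The interferon-stimulated list fell in goblet-like cells too, with a median of −1.13 over 42 genes (adjusted p = 9.75e-47, and adjusted p = 0.434 with an estimated correlation), 1 lower over all genes and 28 when adjusted over the list alone. With the block 17 were lower over all genes, and 36 were lower and 1 higher when adjusted over the list alone. Its sum was 2679 ± 349 CPM in WT and 1556 ± 86.2 CPM in KO (exact permutation p = 0.1). Isg15 stood at 84.0 ± 63.3 against 12.5 ± 3.68 CPM (−2.52 with the block), Ifit1 at 21.8 ± 15.8 against 1.06 ± 1.06 CPM (−4.15) and Oas1a at 32.1 ± 8.93 against 6.06 ± 3.27 CPM (−2.35). Antigen presentation fell with a median of −0.60 over 19 genes (adjusted p = 4.09e-09, and adjusted p = 0.611 with an estimated correlation), with 0 members past over all genes or when adjusted over the list alone, and 8 lower by the latter with the block. Sets with a higher test were Paneth (median 0.15, adjusted p = 0.00373, with defensin UMIs held mostly by few cells, at medians of 6 and 13 per cell and means of 303 and 374), Wnt targets (0.31, adjusted p = 0.00174), enteroendocrine (0.39, adjusted p = 0.0157), stem cell (0.18, adjusted p = 0.0157) and mid villus (0.21, adjusted p = 0.0157). For each of them the call was lost (adjusted p = 0.611 to 0.786 with an estimated correlation). With the block, the stem cell (adjusted p = 0.387) and enteroendocrine (0.0608) lists also no longer passed camera at the preset correlation. The other 16 lists tested in goblet-like cells did not pass, and enterocyte (−0.07), lipid absorption (−0.08), villus bottom (−0.26) and goblet (−0.12) lists had medians under 0 with tests directed up. The wound-associated growth factor gene Areg stood at 395 ± 212 against 132 ± 23.2 CPM and did not pass, and the mucin gene Muc2 had a log2 fold change of −0.01.

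In this class edgeR called 2 of 9620 genes, with 255 at an unadjusted p under 0.05, and DESeq2 called 29 (7 higher and 22 lower). With the block 33 were called, 8 higher and 25 lower. Genes named by rule from it were Nupr1 (591 ± 329 against 147 ± 15.9 CPM, −1.81) and Ddx60 (244 ± 97.3 against 78.5 ± 22.9 CPM, −1.57). Among those higher were Mt1 (104 ± 48.8 against 707 ± 137 CPM, 2.84) and Fabp1 (83.8 ± 28.1 against 175 ± 6.23 CPM, 1.12). Fabp1 is a gene of the enterocyte list and was also higher with the block in enterocyte-like cells. Free RNA from enterocytes was not tested for it, so a change within goblet-like cells is not shown. The count without the block rested on few mice: it was 198 (59 higher and 139 lower) without WT2 and 0 without WT1, WT3, KO1, KO2 or KO3, and both Gip and Rtp4 lost their call without each mouse but WT2. It was also 0 without scaling between libraries, with a 10% mitochondrial limit, over genes of at least 50 CPM, and after thinning to 2000 UMIs.

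Shares of cell classes answer whether the make-up of the sorted epithelium differed with genotype. Enterocyte-like cells made up 71.2 ± 10.0% of WT and 62.2 ± 12.9% of KO cells (exact permutation p = 0.5). An unnamed cluster that scored nearest to enterocytes held 2.51 ± 1.43% and 10.5 ± 0.972% (exact permutation p = 0.1), and with it added the enterocyte-like shares were 73.7 ± 8.78% and 72.7 ± 11.96% (exact permutation p = 0.9). Goblet-like cells made up 13.5 ± 2.21% and 15.5 ± 2.20% (exact permutation p = 0.2), and regenerative-like cells 1.18 ± 0.396% and 1.83 ± 0.322% (exact permutation p = 0.2). Paneth-like cells made up 0.538 ± 0.387% and 1.03 ± 0.255% (exact permutation p = 0.2), enteroendocrine-like cells 1.33 ± 0.510% and 1.45 ± 0.229% (exact permutation p = 0.8) and tuft-like cells 0.760 ± 0.581% and 0.746 ± 0.237% (exact permutation p = 1). Clusters that took no name held 7.18 ± 2.90% and 11.1 ± 1.33% (exact permutation p = 0.2). Directions depended on the settings, for a cause not tested: with each library clustered separately the Paneth-like difference was −0.539 points, and with a 10% mitochondrial limit the enterocyte-like one was 4.01 and the goblet-like one −6.82 points. No class passed a threshold of 0.05, which 3 against 3 mice cannot reach, since the smallest p they allow is 0.1. Of the 21 immune-like WT cells, 20 came from WT1.

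Crypt progenitor-like cells, marked by Olfm4 and cell cycle genes, were found in WT2 and KO2 alone in this clustering. They were 90 of 866 cells in WT2 (10.4%, exact Clopper-Pearson 95% interval 8.44 to 12.6%) and 180 of 995 cells in KO2 (18.1%, 15.7 to 20.6%). In WT1, WT3, KO1 and KO3 there were 0 among 3780 cells, which allows a share of up to 0.0794% of cells so named. Other settings found up to 3 such cells in these 4 mice, and an unnamed cluster scoring nearest to crypt progenitors held 5 WT1, 8 WT3 and 1 KO3 cells and, of its 509 in all, 452 WT cells with no assigned mouse, so the limit covers the reported clustering only. The difference in mean share, 2.57 points (exact permutation p = 1), went from −3.46 without KO2 to 6.03 without WT2. Intervals and limits cover counting error only.

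**Figure D3:**
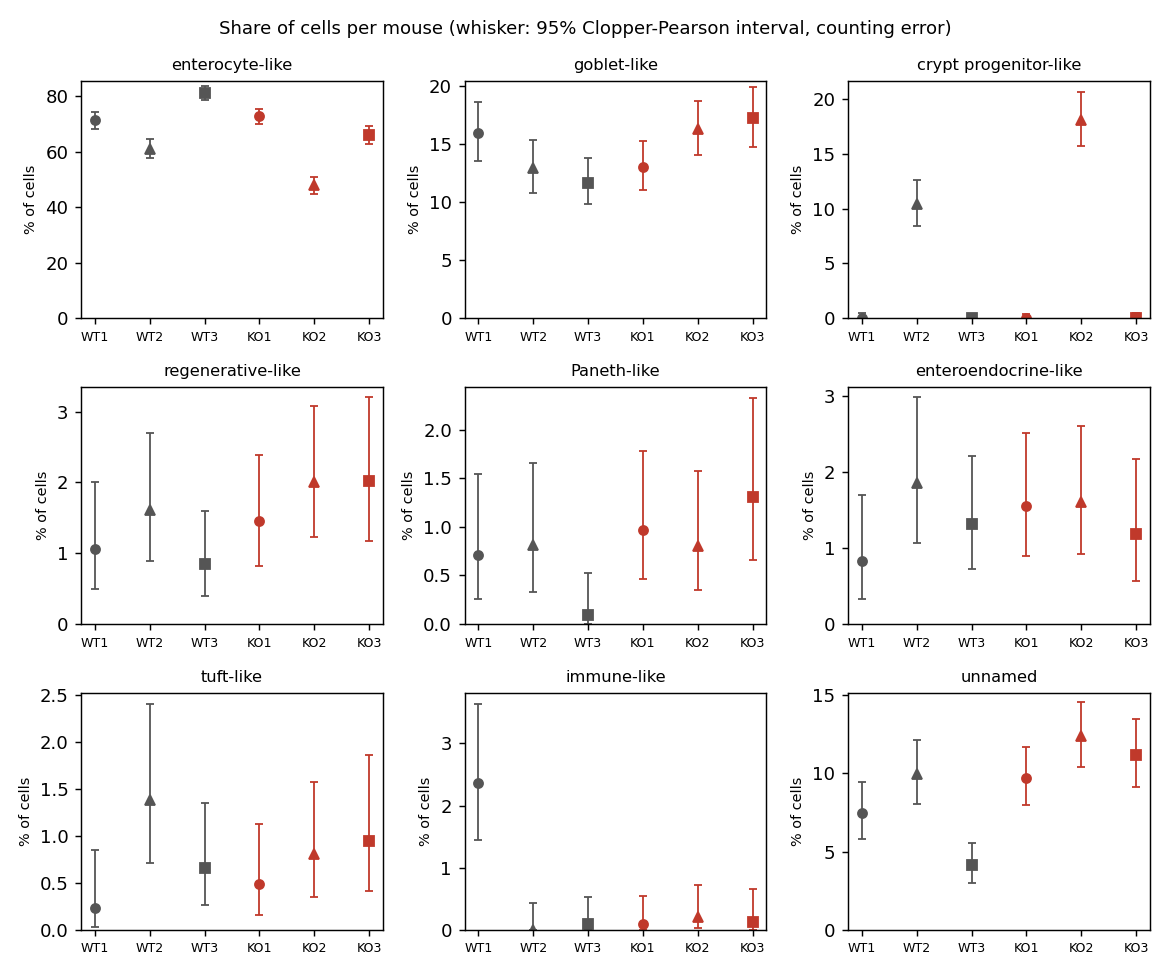
Share of assigned cells in each class (percent), 1 point per WT (grey) or KO (red) mouse, shaped by hashtag number, with whiskers for the Clopper-Pearson 95% interval, which covers counting error only. Crypt progenitor-like cells make up 10.4% in WT2 and 18.1% in KO2 and 0% in the other 4 mice.

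Cells with a UMI were counted at equal depth, which does not separate fewer positive cells from a lower level in all of them. Among enterocyte-like cells thinned to 2000 UMIs, Isg15 was seen in 40.4 ± 7.99% of WT and 16.4 ± 2.75% of KO cells, Ifit1 in 12.3 ± 2.19% and 1.78 ± 0.146%, and Oas1a in 7.13 ± 2.29% and 0.588 ± 0.166%. Irf7 was seen in 49.6 ± 7.64% and 33.2 ± 6.87%, and Zbp1 in 17.8 ± 4.78% and 8.29 ± 1.05%. Crypt progenitor-like cells, low in this program, had Isg15 in 3 of 129 WT cells (2.33%) and 4 of 182 KO cells (2.20%), Irf7 in 7 (5.43%) and 2 (1.10%) and Zbp1 in 2 (1.55%) and 1 (0.549%), at median depths before thinning of 38077 and 68770 UMIs against 8036 and 9130 in enterocyte-like cells. Muc2, a goblet gene that enterocytes should lack, was seen in 19.4% of WT and 21.8% of KO enterocyte-like cells and in 97.5% and 97.6% of goblet-like cells, whose median depths were 27374 and 25388. Gsdmd was seen in 69.2% and 68.3% of enterocyte-like cells, Casp8 in 45.3% and 43.1%, and Ifnlr1 in 8.39 ± 0.983% and 8.08 ± 1.64%. Defa30 was seen in 7.71 ± 1.16% of WT and 31.6 ± 4.07% of KO enterocyte-like cells and in 10.0% and 25.3% of goblet-like cells, which should lack it as well.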

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

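The tests of cell clusters, of free RNA from Paneth cells and of other splits of the mice were set before their results were seen, and the tests of free RNA for the interferon list, of the library as a whole (both replacing earlier versions), of hashtags (likewise), of the mitochondrial limit, of the reach of the isolation and of gut region were chosen only after the results had been seen.

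Differences between cell classes in the response to genotype were found by a test of the interaction between class and genotype. The median of the KO over WT log2 fold change in goblet-like cells minus that in enterocyte-like cells was 0.22 for the interferon-stimulated list (camera on the interaction, adjusted p = 0.0179, and adjusted p = 0.635 with an estimated correlation). It was 0.59 for the villus top list (adjusted p = 2.92e-08), 0.45 for the enterocyte list (adjusted p = 1.80e-04), 0.29 for lipid absorption (adjusted p = 0.00584) and 0.38 for dissociation genes (adjusted p = 0.00119). It was 0.62 for the enteroendocrine list (adjusted p = 0.0136) and 0.32 for Wnt targets (adjusted p = 0.0102). It was −0.30 for proliferation (adjusted p = 0.00584) and −0.30 for oxidative phosphorylation (adjusted p = 0.00451). All 9 rest on the preset correlation, and with an estimated one the adjusted p ran from 0.428 to 0.635. For single genes the interaction test (edgeR) called 0 of 11262. Among cells with no assigned mouse, which no comparison between mice used, 43 were crypt progenitor-like, 41 in the WT and 2 in the KO library. The WT number ran from 8 with the hashtag ratio rule to 220 with each library clustered separately, and with hashtag doublets kept it was 345, of which 95 were doublets and 250 carried no hashtag.

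For the first pattern, the lower interferon-stimulated list in KO enterocyte-like cells, a shift of cells between clusters as the whole cause is argued against, since the list was lower in KO cells within each of the 10 enterocyte-like clusters, with log2 ratios from −1.14 to −0.45 and a median of −0.89. The bound set beforehand, −0.5 in every cluster, was missed by 1 cluster at −0.45 (counting SE 0.03, over pooled cells and not mice) and met by 9. A shift alone was predicted to give ratios near 0 in most clusters, and setting the missed bound aside was decided after the values were seen. An even effect of the library stays open: the list's log2 ratio in crypt progenitor-like cells lay 0.52 above the value that the gene ratios of enterocyte-like cells predict (95% interval over 2000 resamples of the list's genes 0.41 to 0.73), but at equal depth it lay −0.21 from it (−0.52 to 0.49), and in Paneth-like cells 0.53 (0.34 to 0.99) and 0.080 (−0.41 to 0.86). Free RNA shared by all droplets stays open too: taking away as many list UMIs as the class with the fewest holds (immune-like, 18.6 per cell, 38.8% of the 47.9 in WT enterocyte-like cells) lowers the WT list by −0.71, short of the −1.06 in CPM but past the −0.47 in UMIs per cell. Loss of the receptor may account for the pattern, but other differences between the pools (day, housing, handling) cannot be told apart from genotype with 1 pooled library per genotype.

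The second pattern is that crypt progenitor-like cells came from the mice with hashtag number 2. Loss of these cells from the other 4 mice at the mitochondrial limit is argued against, since 0% of assigned crypt progenitor-like cells came from those mice without the limit. Hashtag 2 sticking to crypt cells of any mouse stays open, because with doublets kept 46.3% of WT (94 beside 109 with it alone) and 12.3% of KO crypt progenitor-like cells with hashtag 2 carried a second hashtag, and true doublets carry one as well. Crypts of the other mice not reached by the isolation stays open too: Paneth-like cells, which sit in crypts, made up 0.710% in WT1, 0.971% in KO1 and 1.30% in KO3, near the 0.808% in WT2 and 0.804% in KO2, but 0.0942% (1 of 1062) in WT3, and these are few cells. The restriction was not particular to crypt cells. Cluster 9, an enterocyte-like one, made up 9.01% of cells in WT2 and 13.2% in KO2 and 0.0942 to 0.473% in the other 4 mice. The explanations weighed here concern crypt cells alone and do not cover it. No biological explanation was tested, as the design names no group that separates WT2 and KO2 from the rest.

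The third pattern is the higher count of Paneth defensin UMIs in KO enterocyte-like cells. Free RNA from Paneth cells is a candidate source: median defensin UMIs per cell were 2 in WT and 8 in KO enterocyte-like cells, 3 and 8 in tuft-like, 3 and 9.5 in enteroendocrine-like, 6 and 13 in goblet-like, 4 and 24 in the deeper regenerative-like and 1 and 6 in immune-like cells, and the larger ratio between enteroendocrine-like and enterocyte-like cells was 1.5, which leaves it open, as does the log2 ratio of 1.05 in goblet-like against 1.77 in enterocyte-like cells, further apart than the 0.5 set beforehand. A more distal part of the small intestine sampled in KO mice also stays open: distal genes had a median log2 fold change of 0.90 and proximal genes 0.31, a difference of 0.59, while the distal gene Slc51b stood at −0.47. The leading genes of enterocyte-like cluster 10 included the distal genes Fabp6, Slc10a2 and Slc51b. This cluster made up 0.746 ± 0.467% of WT and 2.07 ± 0.230% of KO cells (exact permutation p = 0.1), higher in each KO mouse. Other enterocyte-like clusters also differed in share with genotype. A change of the defensin genes in KO enterocytes themselves stays untested.

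Other splits of the mice were counted for each number of genes called. In all cells and in enterocyte-like cells the real split called 0 genes by edgeR (232 and 454 at an unadjusted p under 0.05, and 36 and 70 by DESeq2), so 10 of the 10 splits of the 6 mice gave as many, and the highest other was 0. In goblet-like cells the real split gave 2 genes and 2 of the 10 splits gave as many. The other, WT1, WT3 and KO3 against WT2, KO1 and KO2, gave 113, which points to a structure of the samples other than genotype. With the hashtag number as block, the real split gave 152, 2205 and 33 genes, the highest of the other splits that part all 3 pairs was 0 in each case, and 1 of 4 splits gave as many. Neither 10 nor 4 splits can give a share under 0.05. The other 3 differ from the real one by exchanging the genotypes within 1 pair.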

How the results depend on the processing

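The Scrublet scores, leaving out both mice with hashtag 2, the unnamed enterocyte-scoring cluster and every combination with the block were tests chosen only after the result was seen, and the other alternatives were planned. For the fixed lists, 1538 of 1846 values kept their direction and side of the threshold, 206 passed only under the alternative, 60 no longer passed and 42 reversed. For named genes 10451 of 12346 kept both, 1877 passed only under the alternative, 14 no longer passed and 4 reversed. Sign changes where neither value passed count among those kept. Of 152 shares 135 moved by less than the SD between mice and 17 by more, and of 52 shares of cells with a UMI 23 and 29. The interferon-stimulated list ran from −1.47 to −0.73 in all cells, −1.58 to −0.79 in enterocyte-like and −1.31 to −0.39 in goblet-like cells, and passed in 25 of 26, 25 of 26 and 24 of 25 settings. All these passes used camera with the preset correlation of 0.01. The 1 setting that failed in each was the estimated correlation, which was 0.502, 0.368 and 0.485. The counts therefore do not show that the call holds once that correlation is allowed for. Isg15 in enterocyte-like cells ran from −2.82 to −1.93 and passed in 11 of 28 settings, 4 of the 21 without a block. Leaving out scaling between libraries moved the median of all genes from 0.06 to 0.22 in all cells and from 0.07 to 0.23 in enterocyte-like cells. The alternative of batch-corrected clustering was not run, and limma-trend, camera and equal class shares give no value for some results. Depth limits genes of few UMIs per mouse, and the dispersion between mice, 0.226 in all cells against 0.0342 with the block, limits the unblocked count.

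Counts of genes called were 0 in all cells, 0 in enterocyte-like and 2 in goblet-like cells by edgeR without a block (232, 454 and 255 at an unadjusted p under 0.05). In all cells they were 152 with the block, 272 with the block and thinning, 434 with the block and the hashtag ratio rule, 922 with the block in DESeq2, 36 in DESeq2, 6 by limma-trend, 9 without both mice with hashtag 2, and with the block 1212, 55 and 36 without the pair of hashtag 1, 2 and 3. In enterocyte-like cells they were in the same order 2205, 595, 2669, 1498, 70, 38, 1231, and 1713, 2075 and 749, and also 23 after thinning and 1 with a 10% mitochondrial limit. In goblet-like cells they were in that order 33, 5, 35, 40, 29, 8, 939, and 64, 1516 and 56, and also 117 with no mitochondrial limit, 121 with hashtag doublets kept, and 0 without scaling, over genes of at least 50 CPM, with a 10% limit and after thinning. Leaving out 1 mouse gave 0 (each mouse but WT2) to 198 (WT2) there. DESeq2 shared 31, 70 and 26 of its genes with the blocked fit, and the blocked thinned fit shared 95 of 272, 522 of 595 and 4 of 5. Fewer genes are tested after thinning and over 50 CPM; for the rest the cause was not tested.

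With an estimated correlation the interferon-stimulated list no longer passed, at medians of −1.13 in all cells, −1.26 in enterocyte-like and −1.13 in goblet-like cells, nor did antigen presentation at −0.83, −0.65 and −0.60. This lies in the test, which widens the error by the correlation found. Antigen presentation also no longer passed over genes of at least 50 CPM in enterocyte-like cells (−0.26, fewer genes tested), and after thinning in goblet-like cells (−0.22, and −0.19 with the block).

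Lists that reversed in all cells were enteroendocrine (−0.72) and regenerative (0.59) with the block and without pair 1, immune with the ratio rule (0.78, and 0.87 with the block), nutrient transport with a 10% mitochondrial limit (0.17) and the unfolded protein response without scaling (0.14). In enterocyte-like cells they were Wnt targets after thinning (−0.59, −0.62 with the block) and with no mitochondrial limit (−0.23), stem cell after thinning (−0.62, −0.64 with the block) and with the block without pair 2 (−0.19), nutrient transport with the block without pair 2 (0.16) and proliferation with a 10% limit (−0.016). In goblet-like cells they were Paneth with no mitochondrial limit (−0.64) and with doublets kept (−0.71), mid villus with a 10% limit (−0.15) and without the highest 5% of Scrublet scores (−0.069), enterocyte (0.20) and lipid absorption (0.19) with the block without pair 3, proliferation (−0.33) and transit-amplifying (−0.31) with the block without pair 1, and the unfolded protein response without scaling (0.0021). Named genes that reversed there were Dmbt1 (1.26) and Slc12a2 (0.58) with the block without pair 2, Slc12a2 without both mice with hashtag 2 (0.58) and Sox9 with no mitochondrial limit (−1.28). In each of these the cause was not tested.

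Leaving out 1 mouse turned the direction of lists whose members vary with it. In all cells proliferation ran from −2.07 (without KO2) to 2.85 (without WT2), transit-amplifying from −2.22 (KO2) to 3.03 (WT2), regenerative from −0.67 (WT2) to 0.43 (WT1), immune from −0.34 (KO3) to 0.44 (WT1) and nutrient transport from −0.30 (KO3) to 0.13 (KO2). In enterocyte-like cells Wnt targets ran from −0.58 (KO2) to 0.30 (KO1), nutrient transport from −0.16 (KO3) to 0.13 (KO2) and proliferation from −0.07 (KO2) to 1.18 (KO3). In goblet-like cells Paneth ran from −0.078 (KO3) to 0.49 (WT1), enterocyte from −0.38 (WT2) to 0.17 (WT3) and lipid absorption from −0.39 (WT2) to 0.18 (WT3).

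Differences in share (KO minus WT, points) moved by more than the SD for enterocyte-like cells with a 10% mitochondrial limit (4.01 against −8.99), goblet-like cells with that limit (−6.82 against 1.97) and with at least 2000 UMIs (−1.28), and regenerative-like cells with that limit (1.58 against 0.651) and with doublets kept (0.256). Paneth-like cells moved with each library clustered separately (−0.539 against 0.489), with at least 2000 UMIs (1.01) and with no mitochondrial limit (0.835), and immune-like cells with the hashtag ratio rule (0.272 against −0.681). Cells of unnamed clusters moved under 8 settings, from −3.91 with no mitochondrial limit to 12.55 with at least 2000 UMIs (3.90 in the report). Adding the unnamed enterocyte-scoring cluster gave −0.995 for enterocyte-like cells, less than the SD away, and 0 of 10687 genes called (418 at an unadjusted p under 0.05). The cause was not tested.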

Other observations

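The values given here come from no further tests, and the choice to describe these cells and genes was made after the results had been seen.

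Rarer classes had too few cells in some mice for a test of genes. Over the cells of both libraries, the log2 KO over WT ratio of the interferon-stimulated list was −1.53 in tuft-like, −1.19 in regenerative-like, −0.79 in goblet-like and −0.44 in enteroendocrine-like cells, −0.10 in crypt progenitor-like, 0.02 in Paneth-like and 0.30 in immune-like cells. With cells thinned to 2000 UMIs it was −0.36 in crypt progenitor-like and −0.27 in Paneth-like cells, so both values moved with depth. These ratios pool the cells of all mice, so they have no error over mice, and the differences between classes other than enterocyte-like and goblet-like were not tested over mice. The assigned crypt progenitor-like cells come from 1 mouse per genotype, and 41 of the 131 WT cells have no assigned mouse. Of the 59 WT Paneth-like cells 45 have none, and the depths in this class were far apart, with medians of 4579.5 UMIs in WT and 94756 in KO over cells of at least 2000 UMIs. Thinned to that depth, Isg15 was seen in 10 of 56 WT and 2 of 30 KO Paneth-like cells and Irf7 in 12 and 1, so the 0.02 does not compare like cells. The immune-like cells differed in kind, with a UMI of Ptprc in 14.6% of WT and 83.3% of KO cells and one of Muc2 in 78.0% and 8.33% (thinned to 2000 UMIs).

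Cells without an assigned mouse were counted apart. The WT library had 2241 with a median of 4145 UMIs and the KO library 855 with a median of 7229. Among them 1256 WT and 722 KO cells were enterocyte-like, and their interferon-stimulated list stood at 5013 CPM in WT and 2341.5 CPM in KO. The unnamed cluster whose leading genes included the oxidase genes Duox2 and Duoxa2, Clu and Saa1 held 68 assigned WT cells and 301 assigned KO cells, while cluster 6, an enterocyte-like one led by Duoxa2, Saa1, Nos2 and Duox2, held 241 and 22. Sis stood at 4.50 ± 0.262 CPM in WT and 14.9 ± 2.62 CPM in KO goblet-like cells (n = 3 mice each), with a log2 fold change of 1.69 with the block. It was also higher with the block in enterocyte-like cells, and free RNA from these was not tested for it.

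In enterocyte-like cells the fry test for change in either direction gave an adjusted p of 0.0118 for the interferon-stimulated list, 0.0170 for the antigen presentation list and 1.66e-05 for the enteroendocrine list, and the test of a common direction gave 0.0602, 0.0763 and 0.940 in that order. For the interferon-stimulated list these tests gave 0.0828 and 0.199 in all cells and 0.0651 and 0.278 in goblet-like cells.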
